A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

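Total RNA was extracted with hot phenol, cDNA was made with random hexamers and labelled with Cy3 or Cy5, and treated and untreated cells were compared on the same array, per the labels' protocols. The table used holds the authors' processed values, 1 ratio per probe and array, read as log2, as deposited. Background correction, normalization within and between arrays, centring, the filter that emptied cells, the base of the logarithm and the scanner are not given in the sources used here; the base was read as 2. Array medians lay between -0.0779 and -0.000904, so the ratios had been centred near 0 or came out so. No scanner files were used here, so signal over background could not be checked. Empty cells made up 25.8%, 23.9%, 3.02%, 4.94%, 10.2% and 10.3% of the probes on the arrays and swaps of replicates 1, 2 and 3, in this order. All 6 columns of values belonged to the series' samples.

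The direction was not stated for the deposited ratios. By a rule set before the data were examined, an array that correlated above 0.3 with its own dye swap was taken as already turned, and no sign was changed. The orientation treated over untreated was taken from the titles and is called likely.

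Probes were named from the table of the platform's genes, which listed 8462 of the 8480 probes and gave 1469 of them a symbol other than the locus tag; 18 probes were not listed, and no probe had several symbols. A second gene table, of assembly ASM164267v1, shared no identifier with the probes and was not used, so no coordinates are given, and genes without a symbol are given by locus tag. Probes of the same gene were averaged: 8076 genes had 1 probe, 172 had 2 and 20 had 3. Among 121 genes with several tested probes, 9 had probes past the test in opposite directions.

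Each array and its swap were averaged to 1 value per replicate. Genes with a value in each of the 3 replicates were tested with an intercept fit in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation (prior degrees of freedom 3.48), 2-sided, and Benjamini-Hochberg adjustment over the 6604 genes; an adjusted p under 0.05 counted as a change. Fold changes are 2 to the power of the mean log2 ratio, and SDs are over the 3 replicates. The labels state that the 3 materials were prepared independently. On simulated ratios with the real spreads of the 6604 genes, of 200 genes with known shifts the fit found 37.3% at a log2 shift of 0.5, 77.6% at 1 and 97.0% at 2, none in the wrong direction, with 5 calls among unshifted genes. The simulated errors were independent and few genes were shifted, whereas 41.3% of genes were called in the data, so these shares need not carry over.

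Gene lists were fixed before the data were examined, 24 in number, as symbols; 3 of them (ABC transporters, transcriptional regulators and transposases) had no member, because the probe table gives symbols without descriptions. Symbol families were added to 4 of these lists and as 11 further lists, after the probe table's symbols were read and before the genes' values were examined, apart from the first lines of the table and the summary of each column. Lists with at least 5 tested members, 27 of 32 with any member, were tested against the other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. With this test 3 lists were higher and 5 lower. With the correlation estimated from the 3 replicates, a setting with few degrees of freedom and little power, none was (0 of 27). The lists hold only genes with a symbol, which made up 18.7% of tested genes, 17.7% of higher calls and 25.6% of lower calls. Genes with a symbol thus leaned lower as a group, and camera compared the lists with all other genes. The culture was pure, so no cell type markers were set.

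Genes were named by a rule set before the data were examined: the 12 largest rises and 12 largest falls among genes past the test with a symbol and the same sign on all 6 arrays, up to 3 of the largest such members of each list, the largest member of a list without one, and a set of well known genes of peroxide, heat shock, iron, SOS and symbiosis responses. Other members are named as the end of a list's range or as an exception to its direction, and these were chosen after their values were seen.

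Alternatives set before the data were examined were median centring, quantile normalization, scaling to 1 median absolute deviation, all 6 arrays with the replicate as a block (statmod 1.5.0 for the correlation between array and swap, 0.444), a dye term, arrays of 1 dye orientation, stricter and looser filters on empty cells, robust and no moderation, probes on their own, other thresholds, other set tests and leaving out each replicate. A run without the dye-swap array of replicate 2, the array least correlated with the others, was added after seeing the data. A test for a dye effect per gene was planned but is void, since the deposited values leave none: on each of the 5742 probes with 6 values, the mean of the 3 arrays equals the mean of the 3 swaps within 1e-06.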

Results

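*Bradyrhizobium diazoefficiens* USDA 110 is a soil bacterium that fixes nitrogen in soybean root nodules. Its transcripts were measured on 2-colour microarrays, in cells grown in arabinose-gluconate medium and shocked with 10 mM hydrogen peroxide for 10 min, against untreated cells. The labels describe 3 independent biological preparations. Each preparation was hybridised on 1 array with the treated cells in Cy5 and on 1 array with the dyes swapped, which gives 6 arrays and n = 3. Whether the replicates' mean ratios are independent depends on how the deposited values were built, which is not known (see Other observations). The deposited values are log ratios, read here as base 2, for 8480 probes, of which between 256 and 2190 per array were left empty by the authors. The number of arrays limits the precision, and 6604 of the 8268 genes had a value in each replicate and were tested.

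The question asked was which genes the cells turn up or down within minutes of a peroxide shock. Most tested genes for respiration at low oxygen and all for denitrification and nitrate reduction rose, while most genes for ribosomal proteins and for ATP synthase and the aerobic respiratory chain fell. All 20 tested genes of denitrification and nitrate reduction rose, led by norB (blr3215), a subunit of nitric oxide reductase, at a log2 ratio of 3.59 ± 0.52 (SD, n = 3), 12.1-fold. The largest rise among genes with a symbol and the same sign on all 6 arrays was that of msrA (blr7043), a methionine sulfoxide reductase that repairs oxidised protein, at 3.77 ± 0.26, 13.6-fold. The largest fall among such genes was that of flgC (bll5813), a rod protein of the flagellar basal body, at -2.77 ± 0.42, 6.83-fold lower. The signs throughout are likely treated over untreated: the array titles name the shock first, and each array correlated positively with its own swap (r = 0.926, 0.869 and 0.914 in replicates 1, 2 and 3, across probes, which are not independent), so the swaps had already been turned.

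In limma's moderated test with Benjamini-Hochberg adjustment, 2728 genes (41.3% of those tested) changed, 1171 of them higher and 1557 lower. With each array centred on its median the split was 1296 and 1371, so the surplus of lower calls was smaller but remained. Of the 2728 genes, 339 were at least 2-fold higher and 242 at least 2-fold lower, and 87 were at least 4-fold higher against 17 at least 4-fold lower. Of the 1235 tested genes with a symbol, from which the gene lists were drawn, 207 were higher and 399 lower. These shares are the background for the counts of list members below. The sign was the same on all 6 arrays for 2417 of the 2520 changed genes that had a value on each. The replicates' log2 ratios correlated with r = 0.809 (replicates 1 and 2), 0.890 (1 and 3) and 0.892 (2 and 3) across genes. The count rested on the variance pooled over genes and on replicate 3: without moderation of the variance no gene passed (0, with 2428 at an unadjusted p under 0.05), and without replicate 3 the count was 1400.

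**Figure D1:**
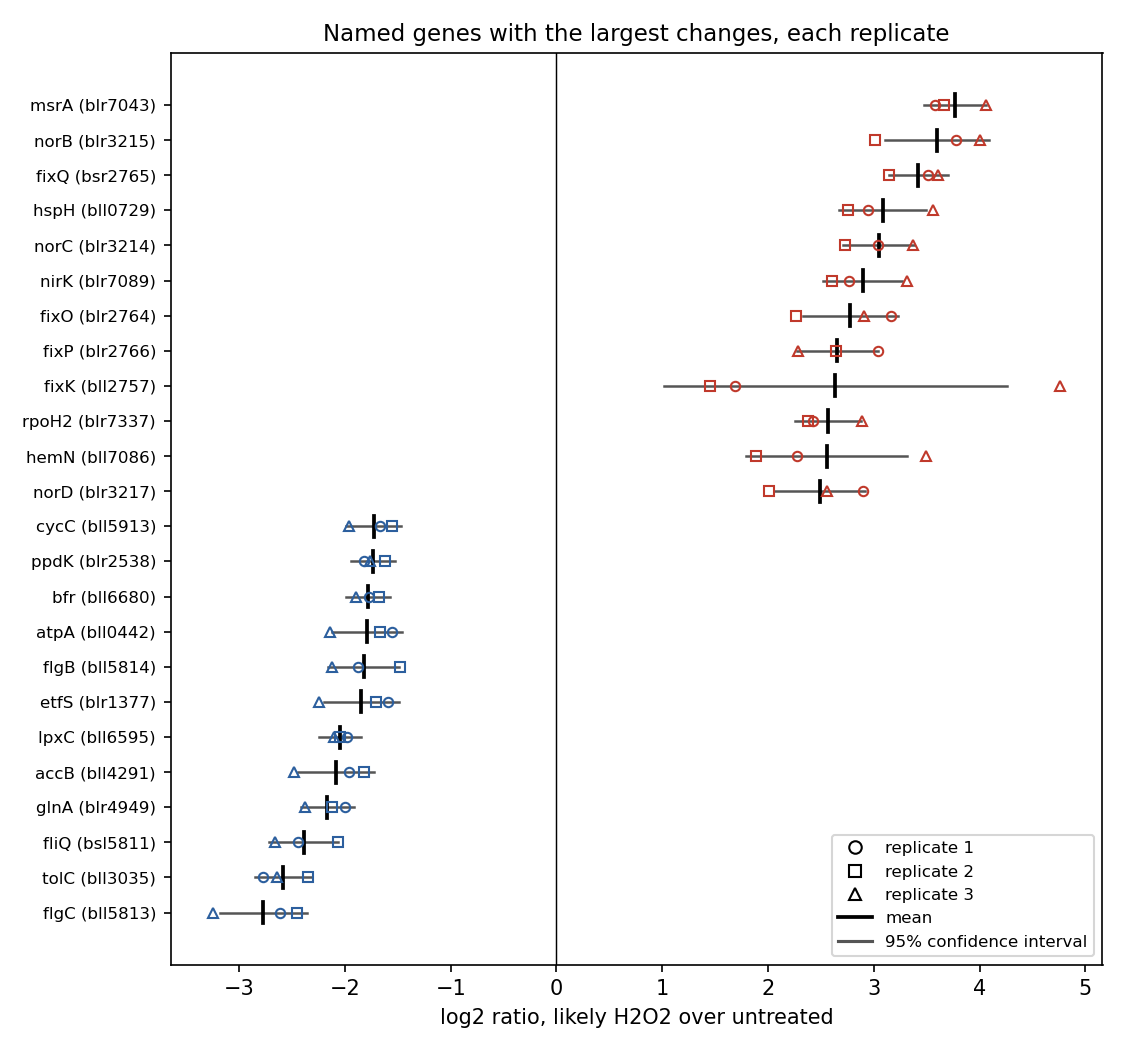
Log2 ratios (x axis, likely treated over untreated) of the 12 genes with the largest rise and the 12 with the largest fall among genes with a symbol and the same sign on all 6 arrays (y axis, symbol and locus tag). Open symbols are the 3 replicates, the black bar is their mean and the grey line limma's 95% confidence interval; replicate 3 of fixK (bll2757) stands at 4.76 and its other replicates at 1.69 and 1.46.

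The genes of the cbb3-type terminal oxidase, which has a high affinity for oxygen, and of its regulators formed a list of 14 tested members. Of these, 12 rose and none fell, over all genes and adjusted over the list alone, with a median log2 ratio of 1.25. The oxidase subunit genes fixQ (bsr2765), fixO (blr2764) and fixP (blr2766) rose by 3.42 ± 0.24, 2.78 ± 0.47 and 2.65 ± 0.38 (SD, n = 3). The gene fixK (bll2757), a regulator of the CRP/FNR family, stood at 2.64 ± 1.85 with limma's adjusted p = 0.0244. Its value came mostly from replicate 3, was 1.57 without it, and its adjusted p was 0.0721 with robust moderation. The response regulator gene fixJ (bll2759) and another gene named fixK (bll3466) did not pass the test, at -0.10 and -0.03. The sensor gene fixL (bll2760) had values on 4 arrays, from -0.46 to 0.21, and was not tested. In limma's camera test with a preset correlation of 0.01 the list was higher than the other genes (adjusted p = 5.31e-06), and not with the correlation estimated from 3 replicates (adjusted p = 0.573 with an estimated correlation).

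Denitrification reduces nitrate stepwise to dinitrogen in place of oxygen. All 20 tested genes of the list of denitrification and nitrate reduction rose, over all genes and adjusted over the list alone, with log2 ratios from 0.53 to 3.59 and a median of 1.91. Beside norB, the genes norC (blr3214) and norD (blr3217) of nitric oxide reductase rose by 3.05 ± 0.32 and 2.49 ± 0.45, and nirK (blr7089), which encodes the copper-containing nitrite reductase, by 2.90 ± 0.37. The smallest rise was that of nasA (blr2809), a nitrate assimilation gene, at 0.53. The list was higher in the camera test (adjusted p = 3.85e-12; adjusted p = 0.573 with an estimated correlation). Its median was 1.98, 1.32 and 2.17 in replicates 1, 2 and 3.

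Of 51 ribosomal protein genes, 33 fell and 4 rose (36 and 5 adjusted over the list alone), with a median of -0.56. The genes rpsG (bll5404), rpsE (bll5383) and rpmJ (bsl7548) fell to -1.25 ± 0.13, -1.20 ± 0.37 and -1.15 ± 0.08 (SD, n = 3), while rpsO (bsl0780) rose to 0.94. Of 19 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 12 fell and none rose (15 and 0 adjusted over the list alone), among them gltX (blr4838) at -1.32 ± 0.24, proS (bll4877) at -1.19 ± 0.08 and glyQ (blr2535) at -0.82 ± 0.33. The call of glyQ was lost without replicate 3, at -0.80. Both lists were lower in the camera test (adjusted p = 5.31e-06 and 0.00390), and neither with an estimated correlation (adjusted p = 0.573 for each). The names of these lists were fixed before the data were examined and their symbols were added from the probe table.

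Of 27 genes of ATP synthase, NADH dehydrogenase and the aa3-type oxidase, 20 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -0.62. The ATP synthase genes atpA (bll0442), atpH (bll0443) and atpC (bll0439) fell to -1.79 ± 0.31, -1.57 ± 0.24 and -1.52 ± 0.19 (SD, n = 3). The list was lower in the camera test (adjusted p = 3.32e-05; adjusted p = 0.573 with an estimated correlation). In the tricarboxylic acid cycle 6 of 12 genes fell (7 adjusted over the list alone), with sdhD (blr0513) at -1.23 ± 0.16 and mdh (bll0456), malate dehydrogenase, at -1.06 ± 0.25. The aconitase gene acnA (bll0466) was its only member that rose, over all genes or over the list alone, to 1.83 ± 0.19, and the list as a whole did not pass the camera test (adjusted p = 0.0986). All 4 tested genes of the list of pentose phosphate and sugar acid catabolism fell, over all genes and adjusted over the list alone, from rpe (blr5680) at -1.07 ± 0.31 to zwf (blr6760), glucose-6-phosphate dehydrogenase, at -0.43 ± 0.08.

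**Figure D2:**
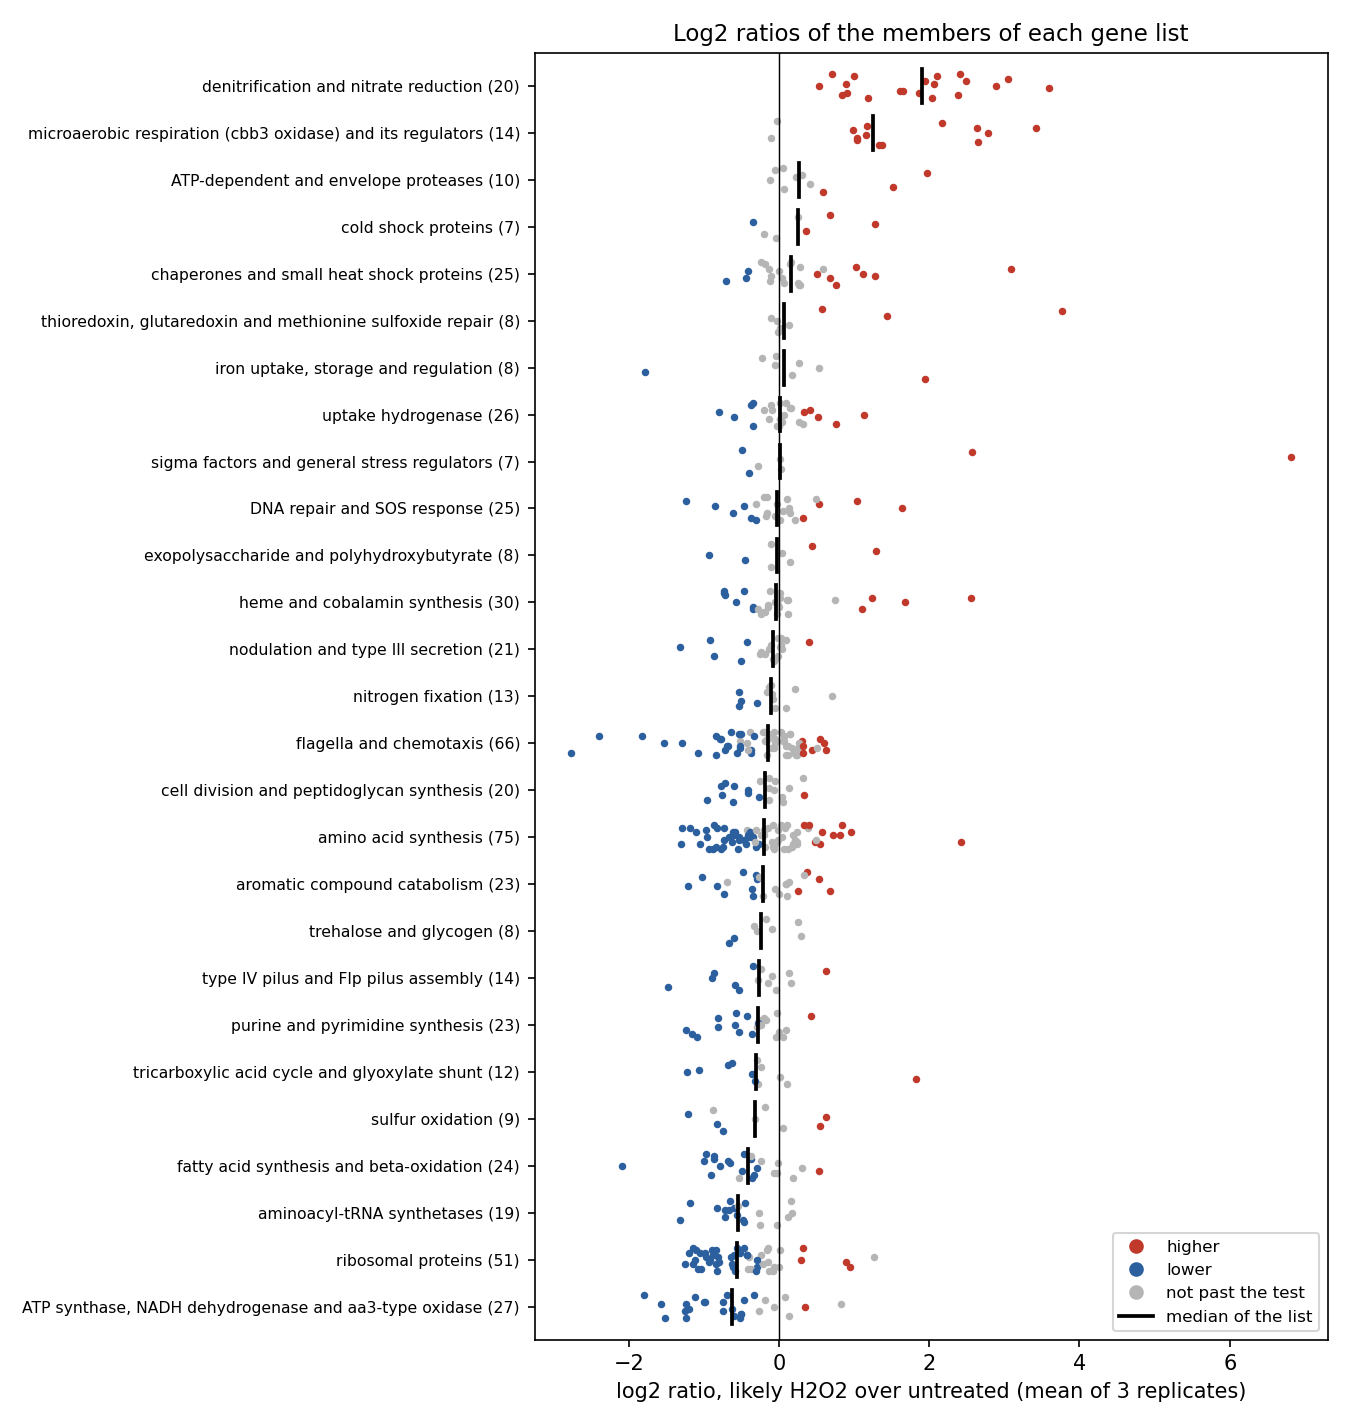
Log2 ratios (x axis, likely treated over untreated, mean of 3 replicates) of the members of each of the 27 gene lists with at least 5 tested members (y axis, number of members in parentheses), ordered by median. Red points are genes past limma's test and higher, blue points past it and lower, grey points not past it, and the black bar is the list's median, from 1.91 for denitrification and nitrate reduction to -0.62 for ATP synthase, NADH dehydrogenase and aa3-type oxidase.

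Of 8 genes of thioredoxin, glutaredoxin and methionine sulfoxide repair, 3 rose and none fell, over all genes and adjusted over the list alone: msrA (blr7043), trxA (bll0751), a thioredoxin, at 1.43 ± 0.33, and a second msrA (blr0834) at 0.57 ± 0.16, which lost its call without replicate 3, at 0.54. Of 25 chaperone and small heat shock genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone). The falls were those of htpG (bll7789) at -0.71 and of the groES genes blr5226 and bsr7532, at -0.41 and -0.43. The genes hspH (bll0729), a small heat shock protein, clpB (blr1404), a disaggregase, and dnaK (blr0678) rose to 3.09 ± 0.42, 1.28 ± 0.44 and 1.12 ± 0.28 (SD, n = 3), whereas none of the 5 groEL genes passed the test. Their values lay between -0.13 and 0.27. Under median centring, and under median centring with scaling, 1 of them (blr6979) passed as higher, at 0.31 and 0.29. Of 10 protease genes, 3 rose, over all genes and adjusted over the list alone: lon (blr6174) at 1.97 ± 0.31, clpS (bll5154) at 1.52 ± 0.42 and hslU (bll0646) at 0.59 ± 0.18, which lost its call without replicate 3, at 0.51. The protease list was higher in the camera test (adjusted p = 0.0444; adjusted p = 0.573 with an estimated correlation; 0.0521 without replicate 3), and the thioredoxin and chaperone lists were not (adjusted p = 0.0939 and 0.0664). Without replicate 3 the chaperone list passed as higher (adjusted p = 0.0148).

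Among regulators, rpoH2 (blr7337), a heat shock sigma factor, rose to 2.57 ± 0.28. The gene rpoH1 (blr5231) stood at 0.02 ± 0.20 without passing the test and rpoH3 (bll0302) fell to -0.40 ± 0.13 (SD, n = 3), a call lost without replicate 1, at -0.35, and without replicate 3, at -0.36. The rise of carQ (bll1028), a symbol given to a sigma factor of the extracytoplasmic function family, was the highest mean of the 6604 genes, at 6.82 ± 0.40, from 4 of the 6 arrays. It was named after its value was seen, because the rule for named genes asks for 6 values. Of the 7 genes of this list 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.532). The iron regulator gene irr (bll0768) rose to 1.94 ± 0.20 and bfr (bll6680), which encodes the iron store bacterioferritin, fell to -1.79 ± 0.11, while fur (bll0797) did not pass the test at 0.27 ± 0.16. These were the only 2 of 8 iron genes past the test, over all genes and adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.600).

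Few genes of peroxide removal could be identified, since 1235 of the 6604 tested genes had a symbol. No gene carried the symbol katG or oxyR, and such genes may be among those tested under a locus tag alone. The superoxide dismutase gene sodF (bll7774) fell to -0.49 ± 0.13, a call lost without replicate 3, at -0.43, and ohr (blr1196), for resistance to organic peroxides, did not pass at 0.24 ± 0.30. They were 2 of 3 tested members of the detoxification list, of which 1 fell, over all genes and adjusted over the list alone. The genes ahpC (bll1777) and ahpD (bll1776) had values on 1 and 2 arrays and were not tested. Both glutathione S-transferase genes, gst (blr2503) and gst (bll2509), fell to -1.05 ± 0.22 and -0.96 ± 0.29 (SD, n = 3), and so they did adjusted over the list alone. Of 3 multidrug efflux genes, acrA (blr1515) and acrB (blr1516), parts of a tripartite pump, rose 2.84-fold and 2.26-fold (log2 SDs 0.21 and 0.11, n = 3), also adjusted over the list alone.

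Genes of DNA repair moved both ways. Of 25 members, 4 rose and 6 fell, over all genes and adjusted over the list alone. These shares were near those over all 6604 tested genes, of which 1171 rose and 1557 fell. Of the 1235 tested genes with a symbol 207 rose and 399 fell, a larger share of falls than in the list, and the difference was not tested. The gene lexA (blr4826), the repressor of the SOS response, rose to 1.63 ± 0.28, recR (bll8114) and recJ (blr4377) fell to -1.23 ± 0.27 and -0.85 ± 0.19, and recA (bll5755) did not pass the test at 0.13 ± 0.22 (SD, n = 3). The list was not shifted in the camera test (adjusted p = 0.991), whose sign, higher, was opposite to that of the list's median of -0.02. The median was 0.02 under median centring.

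Of 66 flagellar and chemotaxis genes, 22 fell and 7 rose, over all genes and adjusted over the list alone. The share that fell was near that among all tested genes with a symbol (399 of 1235) and above that among all tested genes (1557 of 6604). Beside flgC, the genes fliQ (bsl5811), part of the export apparatus, and flgB (bll5814), another rod protein, fell to -2.39 ± 0.30 and -1.82 ± 0.32 (SD, n = 3), and the flagellin gene fliC (bll6855) did not pass the test at -0.10 ± 0.04. The list as a whole was not past the camera test (adjusted p = 0.187). Of 13 members with locus numbers from 5809 to 5837, 11 fell, and of 27 members numbered from 6850 to 6885, 3 fell and 6 rose. These runs were picked after their values were seen.

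Of 13 nitrogen fixation genes 4 fell and none rose (3 and 0 adjusted over the list alone), with fixR (blr2036) at -0.54 ± 0.11, fixX (bsr1775) at -0.53 ± 0.15 and nifK (blr1744) at -0.50 ± 0.28, which lost its call without replicate 3, at -0.49. The nitrogenase reductase gene nifH (blr1769) fell to -0.29 ± 0.12 (limma's adjusted p = 0.0426), and its call was lost under median centring, on the arrays of either dye orientation alone, and without any 1 of the replicates (-0.33, -0.22 and -0.32 without replicates 1, 2 and 3). Of 21 nodulation and type III secretion genes 5 fell and 1 rose (3 and 0 adjusted over the list alone), with nodA (blr2025), which acylates the Nod factor, at -1.31 ± 0.31 and the regulator gene nolA (bll2019) at -0.92 ± 0.20 (SD, n = 3). Neither list passed the camera test (adjusted p = 0.395 and 0.287). A separate list, of iron-sulfur cluster assembly, held 3 tested genes, all named nifS. Of these, blr1756 did not pass the test at -0.14, while blr4342 fell to -0.76 ± 0.05 and blr4338 rose to 0.27 ± 0.07, also adjusted over the list alone. The call of blr4338 was lost without any 1 of the replicates, at 0.26, 0.31 and 0.25. Of 8 genes of exopolysaccharide and polyhydroxybutyrate synthesis 2 rose and 2 fell, over all genes and adjusted over the list alone, from phbC (bll6073), a polyhydroxybutyrate synthase, at 1.29 ± 0.65 to exoB (blr7578) at -0.94 ± 0.24 (camera adjusted p = 0.824, with a median of -0.03 and a mean of 0.04; the median was 0.01 under median centring).

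Outside the lists, the largest falls among genes with a symbol and 6 values of the same sign were those of tolC (bll3035), an outer membrane channel, at -2.59 ± 0.21, glnA (blr4949), glutamine synthetase, at -2.17 ± 0.19, lpxC (bll6595), an early enzyme of lipid A synthesis, at -2.05 ± 0.06, etfS (blr1377), an electron transfer flavoprotein, at -1.85 ± 0.35, ppdK (blr2538), pyruvate phosphate dikinase, at -1.74 ± 0.10, and cycC (bll5913) at -1.73 ± 0.21 (SD, n = 3). The limma adjusted p of these genes lay between 0.000306 and 0.000662.

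Of the 11 lists added from the symbol table, 2 passed the camera test, both lower. Of 24 genes of fatty acid synthesis and beta-oxidation, 15 fell and 1 rose (17 and 2 adjusted over the list alone), with accB (bll4291), the biotin carrier of acetyl-CoA carboxylase, at -2.09 ± 0.35 and fadB (bll3036) at -0.98 ± 0.16 (SD, n = 3). Of 23 genes of purine and pyrimidine synthesis, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with pyrC (blr2555), dihydroorotase, at -1.23 ± 0.15, purA (bll7052), adenylosuccinate synthetase, at -1.16 ± 0.06 and pyrE (blr8134) at -1.09 ± 0.20. The adjusted p were 0.00390 and 0.00577 (adjusted p = 0.573 for each with an estimated correlation).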

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

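Among the 111 genes of the naming rule with 6 array values, 2 had 1 array standing apart from the other arrays, and chance alone does this in about 1 in 20 genes. For clpS (bll5154) the dye-swap array of replicate 2 gave a log2 ratio of 0.60 against 1.43 to 1.91 on the other arrays, a gap of 0.631 of the whole range. For the flagellin gene fliC (bll6855) the dye-swap array of replicate 3 gave -0.00183 against -0.15 to -0.10, a gap of 0.643 of the range, in a gene that did not pass the test. None of 3 summaries per array (probes with a value, median and spread) stood apart in this way. The 3 replicates themselves were too few for such a test, and an array and its swap are not independent.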

How the results depend on the processing

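The run without the dye-swap array of replicate 2 was chosen after the data were seen; the other settings were set before. The count of 2728 changed genes stayed between 1886 (arrays with the treated cells in Cy3 alone) and 3582 (dye term and fixed replicate block) under scaling, dye, filter, robust and probe settings, and was 3066 with a replicate block by duplicateCorrelation and 3151 without that array (1344 higher and 1807 lower). The fixed replicate block takes variation between the biological replicates out of the error, so its 3582 calls are not a test over n = 3. Centring each array on its median gave 1296 higher and 1371 lower, and centring with scaling 1373 and 1436, against 1171 and 1557. Without moderation of the variance 0 genes passed, 0 higher and 0 lower, and 0 at least 2-fold (0 and 0), with 3 values per gene; the cause was not tested. At an adjusted p under 0.01, 1553 genes passed, 687 higher and 866 lower. Leaving out 1 replicate gave 1400 to 2901 genes, 642 to 1254 higher and 758 to 1647 lower, the lowest without replicate 3. At a minimum of 1.5-fold 1390 genes passed, 642 higher and 748 lower, and at 3-fold 187, 142 higher and 45 lower. The test for a dye effect is void, since the deposited values leave none on probes with a value on each array, and its 0 genes say nothing. With 1 replicate left out it found 0 to 2 genes. On such probes the dye difference that remains is then set by the replicate left out, so no conclusion is drawn.

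With an estimated correlation 0 of 27 gene lists passed camera, each of the 8 called lists (denitrification, microaerobic respiration, proteases, ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase, fatty acid synthesis, purine and pyrimidine synthesis) having an adjusted p of 0.573. In this setting camera uses the residual degrees of freedom of 3 replicates, which leave it little power, so 0.573 is not evidence against a list. How far the members' correlation added to this was not tested. The estimated correlations of these 8 lists ran from 0.0379 (proteases) to 0.424 (denitrification). Thioredoxin and cold shock, with estimates of -0.0413 and -0.0780, also stood at 0.573, so this value does not measure how strongly members correlated. With fry, which compares a list with no other genes, 18 lists passed in 1 direction, those not past camera being thioredoxin, sigma factors, nitrogen fixation and cold shock (adjusted p = 0.0202 each), chaperones, flagella and amino acid synthesis (0.0236 each), the tricarboxylic acid cycle (0.0213), sulfur oxidation (0.0375) and aromatic compounds (0.00873). In either direction all 27 passed, those not past camera being thioredoxin, iron, sigma factors, the tricarboxylic acid cycle and aromatic compounds (0.0116 each), chaperones, DNA repair, nitrogen fixation, nodulation and amino acid synthesis (0.0121 each), heme (0.0127), flagella and cold shock (0.0131 each), hydrogenase and pili (0.0167 each), exopolysaccharide (0.0181), trehalose (0.0201), sulfur oxidation (0.0252) and cell division (0.0253). With 41.3% of tested genes called, most lists may pass such a test whatever their members, so passing fry in either direction singles out no list. With 1 replicate left out the camera adjusted p ran from 0.0203 to 0.0521 for proteases, from 0.0148 to 0.0669 for chaperones, from 0.0457 to 0.380 for pili and from 0.0457 to 0.0814 for amino acid synthesis, and the other lists kept their side. Without the dye-swap array of replicate 2 the chaperone list passed as higher (0.0417), and amino acid synthesis stood at 0.165. Of 114 genes (those of the naming rule and carQ), of which 111 or more were tested in each setting, none reversed where tested, which on arrays of 1 dye orientation says little, since on probes with 6 values their mean equals the full mean; 100 lost the call without moderation, 17 without replicate 3, 8 on the arrays with the treated cells in Cy3, and at most 7 under any other setting. No signal over background was at hand, so what dim spots limit could not be checked.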

Other observations

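The comparison of residuals between arrays was chosen after the result was seen; the tests of incomplete probes, of gene neighbours and of sign patterns were set before. The added lists that did not pass camera follow. In heme and cobalamin synthesis 4 of 30 genes rose and 7 fell (4 and 7 adjusted over the list alone), with hemN (bll7086), an oxygen-independent enzyme of heme synthesis, at 2.55 ± 0.84 and hemB (blr5037) at 1.68 ± 0.39 (SD, n = 3), and median and mean differed in sign (-0.04 and 0.08, the test's direction being lower and the median 0.00434 under median centring; adjusted p = 0.640). Of 75 amino acid synthesis genes 33 fell and 10 rose (35 and 10 adjusted over the list alone; adjusted p = 0.0986, and 0.0457 without replicate 1), with metF (bll1419), of the folate branch of methionine synthesis, at 2.42 ± 0.25 and ilvC (bll6497), of branched-chain amino acids, at -1.31 ± 0.41. Of 20 cell division and peptidoglycan genes 9 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.110), led by minE (bsr4213), of the division site selection system, at -0.96 ± 0.22. Of 23 genes of aromatic compound catabolism 9 fell and 4 rose (11 and 5 adjusted over the list alone; adjusted p = 0.479), and the falls included pcaC (blr5669) and pcaH (blr0927) of the protocatechuate branch, at -1.21 ± 0.07 and -1.02 ± 0.11.

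Of 26 uptake hydrogenase genes 5 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.521), from hupJ (bll6934) at 1.13 ± 0.47 to hupS (blr1720), the small subunit, at -0.80 ± 0.19 (SD, n = 3). Of 14 pilus assembly genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.157, and 0.0457 without replicate 1), with ctpC (bll1440) at -1.48 ± 0.38. Of 7 genes named cspA, for cold shock proteins, 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.229), led by bsr3154 at 1.28 ± 0.19. In sulfur oxidation 2 of 9 genes rose and 3 fell (2 and 4 adjusted over the list alone; adjusted p = 0.479), with soxZ (bll1012) at -1.21 ± 0.30, and in trehalose and glycogen metabolism 2 of 8 fell (1 adjusted over the list alone; adjusted p = 0.488), with otsA (bll0322), trehalose phosphate synthase, at -0.67 ± 0.14. Among genes without a symbol the largest rises were those of bll4012 and bll2772, at 6.63 ± 0.51 and 6.14 ± 0.49, and the largest falls those of bll7795 and bsr7796, at -2.94 ± 0.36 and -2.73 ± 0.45; of the 100 largest changes 30 belonged to genes with a symbol.

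On each of the 5742 probes with 6 values the mean of the arrays with the treated cells in Cy5 equalled that of the swaps within 1e-06, whereas the 9 other ways to split 6 arrays 3 against 3 gave median gaps of 0.0854 to 0.140. A dye effect estimated from the deposited values and subtracted does not account for it, since on 0% of the 1562 probes with exactly 2 complete pairs did the dye components sum to 0, and 0 of 2413 incomplete probes had equal means. Subtraction before values were left out stays open, untested. A candidate explanation is that ratios were built from sample levels shared between neighbouring arrays in a loop: residuals of a swap correlated more with the first array of the next replicate than with that of the previous one, by 0.368 on average (from -0.23 to 0.12 against -0.45 to -0.30), but on probes with 6 values both constructions leave the same equality and cannot be told apart. No biological explanation was tested. Arrays of 1 dye orientation, which would share no sample in such a loop, gave 2334 and 1886 changed genes. On probes with 6 values their means equal the full means, so these counts differ there only through the spread. In such a loop the means of an array and its swap would share samples between replicates. The tests with n = 3 would then treat dependent values as independent.

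Genes with neighbouring locus numbers changed together: over 3657 adjacent pairs on the same strand, read from the third letter of the locus tag, the log2 ratios correlated with r = 0.371 (rho = 0.342), and over 1802 pairs on opposite strands with r = 0.192 (rho = 0.109), across genes, which are not independent. A trend along the gene order whatever the strand would give both kinds of pair about the same correlation, and the difference of 0.179 (permutation test with 10000 resamples, p = 1e-04, the smallest they can give, adjusted p = 2e-04) speaks against it as the whole cause. Transcription of neighbouring genes as 1 unit may contribute: same-strand genes 2 numbers apart correlated with r = 0.255 when the gene between them lay on the same strand and 0.0952 when it lay on the other, a difference of 0.160 (permutation p = 0.0110, adjusted over the 2 such tests also 0.0110). Both permutation tests moved the strand label over single pairs, which share genes and are not independent. Their p may therefore be too small, which limits the reading of both differences. Taking the partners' values from different replicates gave r = 0.334 and 0.176 for adjacent pairs. Sequence shared between neighbours was not tested, and the correlation of opposite-strand neighbours stays without a tested explanation.

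Turning the sign of any 1 replicate gave at most 0 genes changed, against 2728 as measured, and 0 against 581 changed at least 2-fold. In both counts 1 of the 4 sign patterns, the real one, gave as many, and 4 patterns are too few for a share under 0.05. Since the replicates' ratios correlated, turning 1 of them lowers the means and raises the spreads. Low counts follow from that alone, and no conclusion is drawn from the contrast.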
